A study of Mus musculus with 24 samples.

How the data were processed

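Messenger RNA of mouse peritoneal macrophages was profiled by polyA-selected, paired-end sequencing in 24 libraries. The libraries fall into 6 groups of 4: M0 (unpolarized), M1 and M2 cells, each without and with ONX-0914, an inhibitor selective for PSMB8, the catalytic LMP7 subunit of the immunoproteasome. Per the labels, the 4 replicates of a group are independent and each pools cells of 2 to 3 mice to reach 50000 cells. Per the labels, M1 cells were treated with LPS and IFN-γ and M2 cells with IL-4. Doses and treatment times are not given in the sources used here.

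The deposited table holds raw counts per Ensembl gene, without normalization, and all of its values are whole numbers. The authors name FastQC 0.11.9, cutadapt 2.8, Bowtie2 2.2.5 and Picard and the mouse build mm10, but not the order or role of each. The counting tool, the strand setting and the annotation release are not given in the sources used here. Of 54532 features, 54409 matched a symbol in GENCODE M21 (GRCm38), which also gave the positions printed below. The 123 features without a symbol held 0.0282% of the counts. No count fell on 25561 features in any library. Total counts per library, in units of 1e6, ran from 18.2 to 22.9.

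Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 6 groups as design, which left 14692 genes holding 99.927% of the counts. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 24 libraries together, with 18 residual degrees of freedom and no replicate block. The 5 pairwise comparisons were ONX-0914 against no inhibitor within M0, M1 and M2, M1 against M0, and M2 against M0. The 3 differences of effects (interaction terms) compared the effect of ONX-0914 between M1 and M0, M2 and M0, and M1 and M2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Standard errors of log2 changes are the log2 change divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts per 1e6 counts), as mean ± SD. At these depths a library with no count of a gene allows up to 3 counts of it at 95% confidence. A fold against a group with no count was computed against 3 counts over the group and written as a lower bound. With 1 to 3 counts in a group, a ratio with its exact 95% counting interval is given. Floors and intervals cover counting error only, not differences between mice or library preparation.

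The comparisons, tests, alternatives, 34 lists of pathways, complexes and cell type markers, and the rule for named genes were fixed before the data were examined. Each list was tested in each of the 8 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 264 tests. The tests were repeated with an estimated correlation and with fry. fry asks whether the members of a list move, on balance, in 1 direction, and its mixed form whether they change in either direction. Neither compares a list with other genes. The list of erythroid markers had 0 tested members. Members are counted as changed when adjusted over all genes, and again when adjusted over the list alone.

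Genes named in the text come from a fixed rule. In each pairwise comparison the rule takes the 8 largest rises and 8 largest falls among called genes. These have a mean of at least 5 CPM in the higher group, all 4 libraries of the higher group above all 4 of the other, and a symbol that is not a clone or predicted name. For each list it takes up to 4 called members with the largest change, and for each difference of effects the 6 largest differences under the same CPM and symbol conditions. It adds a fixed set of genes whatever their result, among them the proteasome catalytic subunits, Nfe2l1, Nfe2l2, Keap1, Sqstm1 and markers of the M1 and M2 states.

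Overlaps of called genes were set beside the count that independence would give. Where 2 comparisons share a group, they were also set beside 10 simulations of unchanged groups and beside 6 ways of dividing the shared group, 2 libraries to each comparison. Alternatives named in advance were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma voom with quality weights, no count filter, a filter of at least 1 CPM in 4 libraries, the libraries of the comparison alone, a replicate block, a minimum log2 change of 1, and leaving out each library in turn. Leaving out each library for the lists and overlaps, DESeq2 size factors for the lists, and leaving out M1 replicate 2 as a doubted library were added after the data were seen. The scale of the levels screened for outlying libraries was changed from unscaled to TMM-scaled CPM after the first screen had been seen. The pipeline was tested on simulated data for ONX-0914 in M0: of 50 genes planted at each size, 25 were called at 1.25-fold, 41 at 1.5-fold, 48 at 2-fold and 50 at 4-fold, and 9 of 173 calls (5.2%) were unchanged genes. No library was left out of the main results.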

Results

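Gene expression was measured in mouse peritoneal macrophages in 3 states: unpolarized (M0), polarized to the inflammatory M1 state with LPS and IFN-γ, and polarized to the alternatively activated M2 state with IL-4. Each state was cultured without or with ONX-0914, a small molecule that inhibits the immunoproteasome, the form of the proteasome that immune cells carry and that cytokines induce. There were 4 libraries in each of the 6 groups, each from pooled cells of 2 to 3 mice. Counts per library, in units of 1e6, were 18.5 to 21.8 in M0 and 18.8 to 19.4 in M0 with ONX-0914. They were 18.2 to 20.96 in M1 and 18.9 to 22.9 with ONX-0914, and 19.1 to 21.5 in M2 and 18.6 to 19.8 with ONX-0914. The principal component that held 70.25% of the variance between libraries set the M1 groups apart from the M0 and M2 groups. M1 replicate 2 stood apart from the other 3 M1 libraries. It had 0.30% of its counts on mitochondrial genes against 1.07% to 1.14%, and 13.1% on the 10 most counted genes against 10.3% to 10.4%. Pairs of M1 libraries correlated across genes at r = 0.976 to 0.991, where pairs within the other groups lay between 0.991 and 0.992, and genes are not independent replicates. Adjusted p-values of genes below are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and those of lists are from camera. A list call given with a single p also held with an estimated correlation.

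**Figure D1:**
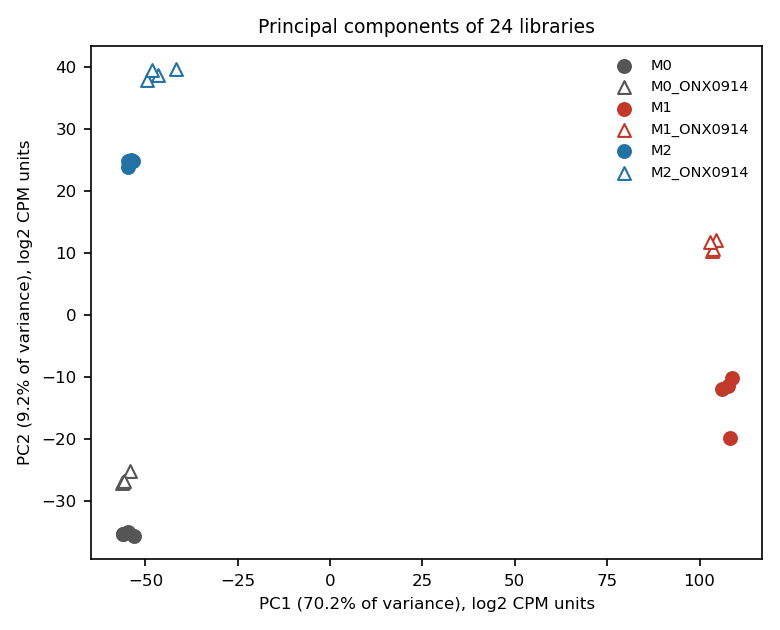
Principal components of the 24 libraries, with PC1 on the horizontal and PC2 on the vertical axis, both in log2 CPM units; each point is a library, filled circles are cultures without and open triangles cultures with ONX-0914. PC1 holds 70.25% and PC2 9.20% of the variance, and the 8 M1 libraries lie apart from the other 16 on PC1.

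The comparison of M1 with M0 asks which genes the inflammatory polarization changed, and so shows what state the inhibitor met. Inflammatory cytokines and mediators rose together: all 17 tested members of the list rose (17 adjusted over the list alone), with a median log2 change of 8.66 (adjusted p = 4.11e-35). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), which encodes inducible nitric oxide synthase, had 4 counts over the M0 libraries and 1980 ± 314 CPM in M1 (SD, n = 4, adjusted p = 1.67e-26). Tnf rose from 5.02 ± 0.526 to 2360 ± 100 CPM (adjusted p = 1.29e-28). Il12b, a subunit of the cytokine IL-12, had no count in M0 and 333 ± 44.4 CPM in M1, at least 9580-fold higher over the group, a bound that lies above the list median. Il1b had 3 counts in M0 and 43.0 ± 7.82 CPM in M1, a ratio of 1220 with a counting interval of 418 to 5940. Without M0 replicate 1 its log2 change was 10.95, against 10.03.

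The interferon and antigen presentation genes rose with them. All 28 type I interferon-stimulated genes rose (28 adjusted over the list alone, median 6.94), as did all 17 interferon-gamma-inducible GTPases (17 alone, median 6.43), all 14 genes of MHC class I presentation (14 alone, median 2.88) and all 5 immunoproteasome and PA28 genes (5 alone, median 3.09). Mx1, an antiviral GTPase, rose from 0.627 ± 0.167 to 1240 ± 5.42 CPM, Gbp5 from 2.17 ± 0.375 to 2010 ± 121 CPM, and Tap1, a peptide transporter for MHC class I, from 33.8 ± 2.15 to 1060 ± 88.4 CPM (n = 4). Psmb8 (ENSMUSG00000024338, chromosome 17, 34197721 to 34201454), Psmb9 (ENSMUSG00000096727, chromosome 17, 34181987 to 34187764) and Psmb10 (ENSMUSG00000031897, chromosome 8, 105935735 to 105938444) encode the catalytic subunits of the immunoproteasome. They rose from 52.0 ± 3.54 to 372 ± 44.8 CPM, from 18 ± 2.37 to 229 ± 38.1 CPM and from 62.9 ± 4.86 to 534 ± 92.3 CPM. The list adjusted p was 1.19e-55 for the interferon-stimulated genes, 9.83e-47 for the GTPases, 5.73e-23 for MHC class I and 1.71e-09 for the immunoproteasome.

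The same comparison changed the M1 signalling and chemokine genes. All 19 M1 surface and signalling markers (19 adjusted over the list alone) and all 16 NF-kappaB feedback targets (16 alone) rose, and 15 of 17 chemokines rose while 1 fell (15 and 1 alone), with adjusted p of 4.96e-31, 1.79e-28 and 6.05e-22. Cd40, a costimulatory receptor, rose from 1.44 ± 0.374 to 1560 ± 192 CPM, and Cxcl9, a chemokine, from 0.0851 ± 0.1 to 1200 ± 245 CPM (log2 13.74, and 14.49 without M0 replicate 3). MHC class II genes rose for 8 of 10 members (8 up and 1 down alone, adjusted p = 1.23e-05). Beside them, summed markers of other cells were, in M0 and in M1, 116 and 87.6 CPM for B cells, 3.73 and 10.8 for dendritic cells, 5.25 and 21.6 for T and NK cells, 4.67 and 25.2 for mast cells and basophils, and 53.9 and 149 for neutrophils. None of these lists passed camera, which could use only 2 of 17 T and NK cell markers. It used 4 of 11 mast cell and basophil, 4 of 12 neutrophil and 4 of 9 dendritic cell markers. The sums hold all members and were not themselves tested. All 4 tested dendritic cell markers rose (4 alone, adjusted p = 0.493 for the list). Of 17 glycolysis genes, 13 rose (13 alone, adjusted p = 0.000494, and adjusted p = 0.421 with an estimated correlation). Hk2, a hexokinase, rose from 67.4 ± 3.20 to 255 ± 34.6 CPM. Sqstm1 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827), which encodes the autophagy receptor p62, rose from 672 ± 37.0 to 1570 ± 156 CPM. Keap1, the repressor of NRF2, rose from 52.2 ± 3.76 to 175 ± 25.9 CPM, and Hmox1, a heme oxygenase, from 321 ± 17.0 to 650 ± 48.6 CPM. Genes of the M2 state did not fall as a group. Arg1, an arginase (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), fell from 72.5 ± 6.87 to 8.57 ± 0.961 CPM. Mrc1, the mannose receptor, fell from 121 ± 5.55 to 48.5 ± 4.98 CPM. Chil3 had 6.05 ± 1.14 CPM in M0 and 6.51 ± 1.01 in M1, and Retnla 0.598 ± 0.185 and 0.661 ± 0.487. The summed level of the IL-4-induced list, itself not tested, was 1070 ± 21.1 CPM in M0 and 2493 ± 230 in M1. Lists whose call was lost with an estimated correlation included the 20S core, 14 of 14 up (14 alone, adjusted p = 1.1e-06, then adjusted p = 0.162 with an estimated correlation), and the 19S particle, 18 of 18 (18 alone, 0.000323, then 0.27). They also included ATF4 genes, 17 up and 1 down of 20 (17 and 1 alone, 0.00234, then 0.388), and heat shock genes, 14 up and 4 down of 20 (14 and 5 alone, 0.02, then 0.243). Of all genes tested, 10114 changed, 5084 upward and 5030 downward, and 4152 of them by at least 1 on the log2 scale.

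The comparison of M2 with M0 asks which genes the alternative polarization changed. Of 23 genes that IL-4 is known to induce, 22 rose (23 adjusted over the list alone, median log2 change 4.23, adjusted p = 3.28e-120). Chil3, a chitinase-like protein, rose from 6.05 ± 1.14 to 1560 ± 51.2 CPM (n = 4, adjusted p = 2.05e-27), and Arg1 from 72.5 ± 6.87 to 1950 ± 156 CPM (adjusted p = 2.62e-22). Mrc1 rose from 121 ± 5.55 to 517 ± 29.5 CPM, Retnla from 0.598 ± 0.185 to 5.32 ± 0.692 CPM, and Pdcd1lg2, a ligand of the PD-1 receptor, from 0.365 ± 0.0981 to 32.2 ± 3.12 CPM. Reads may be shared between Chil3 and its paralog Chil4, which had no count in M0 and was at least 98.1-fold higher over the group. Matrix proteases and inhibitors rose for 9 and fell for 3 of 19 members (9 and 4 alone, adjusted p = 2.77e-05). Mmp13, a collagenase, rose from 4.24 ± 0.422 to 128 ± 2.27 CPM. Genes of the ATF4 integrated stress response rose for 17 and fell for 1 of 20 (18 and 1 alone, adjusted p = 1.29e-10). Psat1, an enzyme of serine synthesis, rose from 59.9 ± 3.34 to 133 ± 5.46 CPM.

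NRF2 antioxidant targets fell in M2 for 14 and rose for 2 of 26 members (15 and 2 adjusted over the list alone, adjusted p = 0.000293, and adjusted p = 0.116 with an estimated correlation). Fth1, a ferritin chain, fell from 12600 ± 438 to 6610 ± 329 CPM. Of 20 genes of the ER unfolded protein response, 9 rose and 1 fell (11 and 1 alone, adjusted p = 0.00737, and adjusted p = 0.116 with an estimated correlation). Pdia4 rose from 71.5 ± 1.75 to 309 ± 23.1 CPM. Cell cycle genes rose for 11 of 25 (12 alone, adjusted p = 0.0324, and adjusted p = 0.388 with an estimated correlation), and that list call ended without M2 replicate 2 (median 0.194 against 0.253) or M1 replicate 2. The immunoproteasome subunits did not move alike: Psmb10 rose from 62.9 ± 4.86 to 213 ± 9.52 CPM (adjusted p = 2.29e-15), while Psmb8 (adjusted p = 0.484) and Psmb9 (adjusted p = 0.334) had 49.5 ± 2.34 and 19.6 ± 1.49 CPM in M2. In all, 5315 genes changed, 2744 upward and 2571 downward. Of the genes called in both polarized states, 2979 moved in the same direction, where independence would give 1830, and 1338 in opposite directions. With 2 of the shared M0 libraries given to each comparison, 2197 moved in the same and 1050 in opposite directions on average. Simulated groups without change gave at most 1 gene moved in the same direction. They called only 1.5 genes on average for M1 against M0, so they cannot show how shared libraries act among changed genes.

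ONX-0914 in M0 asks what the inhibitor changed in unpolarized cells. Genes of the proteasome itself rose: all 14 subunits of the 20S core (14 adjusted over the list alone, median log2 change 0.82, adjusted p = 5.14e-62) and 17 of 18 of the 19S regulatory particle (17 alone, median 0.97, adjusted p = 1.81e-102). Psma5 rose from 44.6 ± 1.36 to 125 ± 7.74 CPM (SD, n = 4) and Psmd11 from 55.9 ± 2.58 to 136 ± 5.55 CPM. Psmb5 (ENSMUSG00000022193, chromosome 14, 54614119 to 54618022) and Psmb7, catalytic subunits of the constitutive proteasome, rose from 98.2 ± 10.6 to 159 ± 7.04 CPM and from 55.1 ± 4.77 to 100 ± 6.06 CPM. Their immunoproteasome counterparts moved the other way, with Psmb8 falling from 52.0 ± 3.54 to 41.7 ± 1.97 CPM (adjusted p = 0.00249) and Psmb10 from 62.9 ± 4.86 to 50.3 ± 1.68 CPM (adjusted p = 0.00769). Psmb9 had 18 ± 2.37 and 15.5 ± 1.24 CPM (log2 difference -0.21, adjusted p = 0.164), and it passed without M0 replicate 4 (-0.30) or without M1 replicate 2 (-0.21). The list of 5 immunoproteasome and PA28 genes fell for 3 members (4 alone, adjusted p = 0.0417, and adjusted p = 0.431 with an estimated correlation). Its median of -0.32 lost the call without M0 replicate 1 (-0.28), M0 replicate 2 (-0.25), M0 with ONX-0914 replicate 1 (-0.23) or replicate 4 (-0.29).

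The largest rise in M0 was in Uchl1 (ENSMUSG00000029223, chromosome 5, 66676091 to 66687234), which encodes a deubiquitinase and rose from 1.77 ± 0.356 to 46.4 ± 2.51 CPM (adjusted p = 3.14e-21). Nol3, an inhibitor of apoptosis (ENSMUSG00000014776, chromosome 8, 105276140 to 105281939), and Afp, the alpha-fetoprotein gene (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907), followed with log2 changes of 3.62 ± 0.218 and 3.32 ± 0.2 (SE). Nfe2l1 (ENSMUSG00000038615, chromosome 11, 96817414 to 96829968), which encodes NRF1, a transcription factor of proteasome genes, fell from 298 ± 8.86 to 209 ± 10.2 CPM (adjusted p = 8.02e-08). Sqstm1 rose from 672 ± 37.0 to 847 ± 24.6 CPM (adjusted p = 6.74e-05), and Gclm, a subunit of the enzyme that makes glutathione precursors, from 49.7 ± 1.20 to 70.2 ± 2.27 CPM (adjusted p = 1.78e-06). Of 26 NRF2 antioxidant targets, 13 rose and 4 fell (13 and 5 alone, adjusted p = 0.0228, and adjusted p = 0.365 with an estimated correlation), with Me1, malic enzyme, up from 6.68 ± 0.952 to 17.2 ± 1.78 CPM and Slc7a11, the cystine transporter, down from 43.4 ± 6.60 to 18.2 ± 1.18 CPM. Hmox1 had 321 ± 17.0 and 317 ± 17.8 CPM (adjusted p = 0.864). Cytosolic heat shock genes rose for 8 and fell for 2 of 20 (10 and 3 alone, adjusted p = 0.003, and adjusted p = 0.139 with an estimated correlation). Hsp90ab1 rose from 940 ± 18.5 to 1290 ± 33.4 CPM.

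Genes of the integrated stress response, sterol synthesis and MHC class II fell in M0. ATF4 integrated stress response genes fell for 15 and rose for 2 of 20 (15 and 2 adjusted over the list alone, median -0.60, adjusted p = 1.8e-19). Trib3, a pseudokinase, fell from 30.0 ± 4.63 to 11.9 ± 2.07 CPM and Mthfd2, a mitochondrial folate enzyme, from 104 ± 5.70 to 51.3 ± 6.37 CPM. Of 18 cholesterol synthesis genes, 17 fell (17 alone, median -0.56, adjusted p = 1.07e-21). Mvd fell from 48.8 ± 0.961 to 30.4 ± 1.56 CPM. ER unfolded protein response genes fell for 9 of 20 (10 down and 1 up alone, adjusted p = 0.00342, and adjusted p = 0.0854 with an estimated correlation). NF-kappaB feedback targets fell for 7 of 16 (8 alone, adjusted p = 0.0118, and adjusted p = 0.431 with an estimated correlation). Nfkb2 fell from 53.7 ± 4.22 to 44.2 ± 2.33 CPM. MHC class II genes fell for 9 of 10 members (9 alone, median -1.41, adjusted p = 3.35e-23). H2-Aa fell from 21.8 ± 1.56 to 5.64 ± 0.635 CPM. B cells also carry MHC class II, and all 11 tested B cell markers fell as well (11 alone, median -1.88, adjusted p = 2.25e-14). Their summed level, most of it Cd22 without the inhibitor, went from 116 ± 4.41 to 64.6 ± 2.97 CPM. Matrix proteases and inhibitors rose for 7 and fell for 3 of 19 (8 and 4 alone, adjusted p = 0.0105, and adjusted p = 0.116 with an estimated correlation). Mmp12, macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose from 4720 ± 110 to 7300 ± 623 CPM (adjusted p = 4.85e-07). In all, 3079 genes changed, 1401 upward and 1678 downward. Of the markers of the polarized states, Tnf had 5.02 ± 0.526 and 4 ± 0.883 CPM (adjusted p = 0.0625), and it passed without M0 replicate 1 (log2 -0.38), M0 with ONX-0914 replicate 2 (-0.46) or M1 replicate 2 (-0.33).

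**Figure D2:**
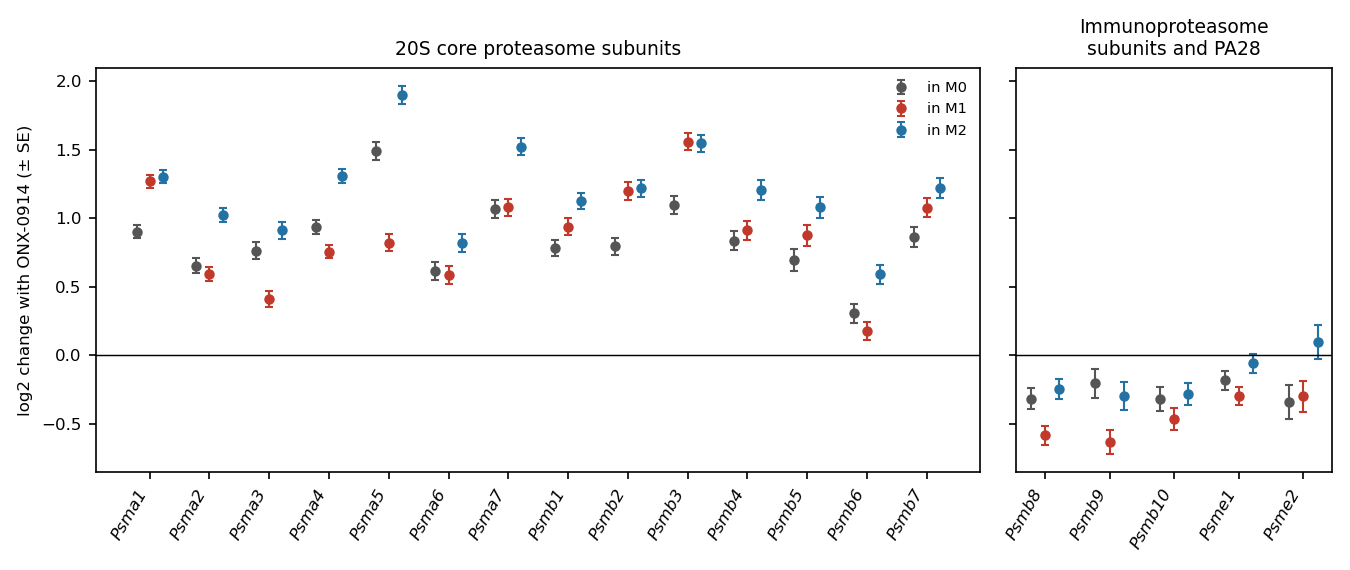
Change of proteasome subunit genes with ONX-0914 in M0, M1 and M2, as log2 change ± SE on the vertical axis against the gene, from 4 libraries per group; the left panel holds the 20S core and the right panel the immunoproteasome and PA28 genes. All 14 core genes lie above 0 in the 3 states, and Psmb8, Psmb9 and Psmb10 lie below 0 in each, with Psmb9 in M0 not past the test (adjusted p = 0.164).

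ONX-0914 in M1 asks what the inhibitor changed in inflammatory macrophages, the state named in the title of the series. More members fell than rose in the lists of cytokines, M1 markers and NF-kappaB feedback targets, but the M1 programme did not move uniformly. Nos2 fell from 1980 ± 314 to 885 ± 94.6 CPM (SD, n = 4, adjusted p = 1.39e-10) and Ptgs2, the inducible cyclooxygenase, from 867 ± 150 to 537 ± 21.2 CPM, while Tnf had 2360 ± 100 and 2260 ± 84.8 CPM (adjusted p = 0.581) and Il1b 43.0 ± 7.82 and 40.4 ± 6.76 CPM (adjusted p = 0.587). Il12a, the other subunit of IL-12, fell from 44.3 ± 5.21 to 22.9 ± 2.71 CPM. Il12b fell from 333 ± 44.4 to 268 ± 36.8 CPM (log2 -0.31, adjusted p = 0.0159). This call ended without M1 replicate 1 (-0.25), M1 replicate 3 (-0.26) or M1 with ONX-0914 replicate 4 (-0.22), and with the libraries of the comparison alone (-0.22). Il6 had 98.9 ± 36.3 and 86.7 ± 8.47 CPM (log2 -0.19, adjusted p = 0.425), and without M1 replicate 2 it passed as lower (-0.42). Over the list of 17 inflammatory cytokines and mediators, 10 fell and 2 rose (10 and 3 adjusted over the list alone, adjusted p = 0.106), and the list passed without M1 replicate 2 (median -0.29 against -0.31).

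Called surface and signalling genes of M1 cells mostly fell, while chemokines went both ways. M1 surface and signalling markers fell for 12 and rose for 1 of 19 (12 and 1 adjusted over the list alone, adjusted p = 0.00224, and adjusted p = 0.0708 with an estimated correlation). Fpr1, a formyl peptide receptor, fell from 23.1 ± 1.41 to 4.62 ± 0.835 CPM. Fcgr1, a high-affinity IgG receptor, fell from 282 ± 44.1 to 64.9 ± 9.39 CPM, and Kcnn4, a potassium channel, from 168 ± 35.5 to 35.4 ± 3.99 CPM. NF-kappaB feedback targets fell for 13 of 16 (13 alone, adjusted p = 9.99e-05, and adjusted p = 0.202 with an estimated correlation). Nfkb2 fell from 705 ± 60.3 to 449 ± 18.9 CPM. Chemokines rose for 7 and fell for 5 of 17 (7 and 6 alone, adjusted p = 0.368), and the risers included Cxcl2, which draws neutrophils, from 316 ± 51.3 to 584 ± 121 CPM. Interferon-gamma-inducible GTPases fell for 10 of 17 (10 alone, adjusted p = 0.117), and this list passed without M1 replicate 2 (median -0.34 against -0.25). Glycolysis genes fell for 13 and rose for 3 of 17 (13 and 3 alone, adjusted p = 3.09e-08, and adjusted p = 0.158 with an estimated correlation). Among them Slc16a3, a lactate transporter, fell from 159 ± 22.9 to 37.0 ± 4.41 CPM, and Pfkl, a phosphofructokinase, from 211 ± 36.4 to 61.7 ± 7.62 CPM.

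Proteasome, heat shock and antioxidant genes rose in M1. All 14 subunits of the 20S core (14 adjusted over the list alone, median 0.89, adjusted p = 1.79e-28) and 17 of 18 of the 19S particle (17 alone, median 1.24, adjusted p = 2.66e-72) rose, Psmc6 from 108 ± 25 to 382 ± 10.2 CPM. Psmb6 was the least changed core subunit, at log2 0.18 (adjusted p = 0.0388), and it lost the call without each of M1 replicates 1, 3 and 4 (0.13, 0.14 and 0.15) and each library of M1 with ONX-0914 (0.16 to 0.18), and had 0.29 without M1 replicate 2. The 5 immunoproteasome and PA28 genes all fell (5 alone, median -0.47, adjusted p = 0.0417, and adjusted p = 0.431 with an estimated correlation). Psmb8 fell from 372 ± 44.8 to 248 ± 11.1 CPM and Psmb9 from 229 ± 38.1 to 147 ± 1.71 CPM. That list call ended without M1 with ONX-0914 replicate 1 (median -0.43) or replicate 2 (-0.44). Of 20 cytosolic heat shock genes, 18 rose (18 alone, median 0.62, adjusted p = 1.46e-24). Hspa1b rose from 25.7 ± 3.02 to 131 ± 9.17 CPM, with reads possibly shared with its near-identical paralog Hspa1a. NRF2 antioxidant targets rose for 13 and fell for 5 of 26 (13 and 5 alone, adjusted p = 2.75e-09). Gclm rose from 92.7 ± 11.3 to 288 ± 8.88 CPM and Srxn1, sulfiredoxin, from 193 ± 8.18 to 615 ± 13.1 CPM. Sqstm1 rose from 1570 ± 156 to 3570 ± 52.7 CPM (adjusted p = 1.7e-15), and Nqo1, a quinone reductase, from 4.01 ± 0.615 to 8.16 ± 0.734 CPM. The gene of NRF2 itself, Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641), fell from 454 ± 19.8 to 329 ± 13.4 CPM (adjusted p = 4.83e-09), and Nfe2l1 from 600 ± 57.6 to 495 ± 22.1 CPM (log2 -0.28, adjusted p = 0.000165). That call ended with the libraries of the comparison alone (-0.18).

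Growth, sterol and antigen presentation genes fell in M1. All 18 cholesterol synthesis genes fell (18 adjusted over the list alone, median -0.69, adjusted p = 1.03e-11). Stard4 fell from 19.5 ± 1.51 to 8.19 ± 0.594 CPM. Cell cycle genes fell for 20 of 25 (23 alone, median -0.51, adjusted p = 0.000962, and adjusted p = 0.158 with an estimated correlation). Mcm5, a replication helicase subunit, fell from 14.3 ± 2.90 to 7.97 ± 0.574 CPM. MHC class I genes fell for 9 and rose for 1 of 14 (9 and 2 alone, adjusted p = 0.0449, and adjusted p = 0.489 with an estimated correlation). Tap2 fell from 279 ± 27.8 to 192 ± 11.3 CPM. That list call, with a median of -0.27, ended without M1 replicate 2 (-0.24) or M1 with ONX-0914 replicate 1 (-0.26), replicate 2 (-0.26) or replicate 3 (-0.27). MHC class II genes fell for 7 of 10 (8 alone, median -0.76, adjusted p = 6.8e-05). H2-Aa fell from 91.9 ± 3.90 to 46.7 ± 3.07 CPM and Ciita, its master regulator, from 31.1 ± 4.30 to 15.2 ± 2.52 CPM. Beside them, 10 of 11 B cell markers fell (11 alone, median -2.10, adjusted p = 0.000208), their sum from 87.6 ± 6.64 to 44.2 ± 2.19 CPM. ATF4 integrated stress response genes rose for 9 and fell for 5 of 20 (9 and 5 alone, adjusted p = 0.0208, and adjusted p = 0.539 with an estimated correlation), with Slc3a2, an amino acid transporter chain, up from 711 ± 79.1 to 1290 ± 30.5 CPM. The autophagy list had 8 risers and 10 fallers of 27 (8 and 11 alone), a median of -0.07, a mean of 0.08 and an upward test at adjusted p = 0.0457, and adjusted p = 0.388 with an estimated correlation. That call ended without M1 replicate 3 (median -0.08), M1 replicate 4 (-0.09) or M1 with ONX-0914 replicate 3 (-0.06).

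In all, 6514 genes changed with ONX-0914 in M1, 2438 upward and 4076 downward, and 950 by at least 1 on the log2 scale. Of called genes 37.4% were higher here, 38.5% with DESeq2 size factors in place of TMM, and 51.9% with the libraries of the comparison alone, which shifted the median of all genes by 0.0927 in log2. Uchl1 was again among the largest rises, from 2.95 ± 0.669 to 101 ± 6.91 CPM, and Sla, an adaptor of immune receptor signalling, had the largest fall among genes with a mean of at least 5 CPM that met the rule for named genes, from 21.2 ± 4.04 to 2.63 ± 0.246 CPM. Of the 5084 genes higher in M1 than in M0, 1962 (38.6%) fell with ONX-0914, where independence would give 1410.5, and 818 (16.1%) rose further, where it would give 844. Of the 5030 lower genes, 908 (18.1%) rose and 1336 (26.6%) fell further, beside 835 and 1395.5 under independence. The M1 libraries enter both comparisons, and with 2 of them given to each, 2327 genes moved against the polarization and 1922 with it on average, where all libraries gave 2870 and 2154. Simulated groups without change gave at most 1 gene moved against it. They called only 2.9 genes on average for M1 against M0, so they cannot show how shared libraries act among changed genes.

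**Figure D3:**
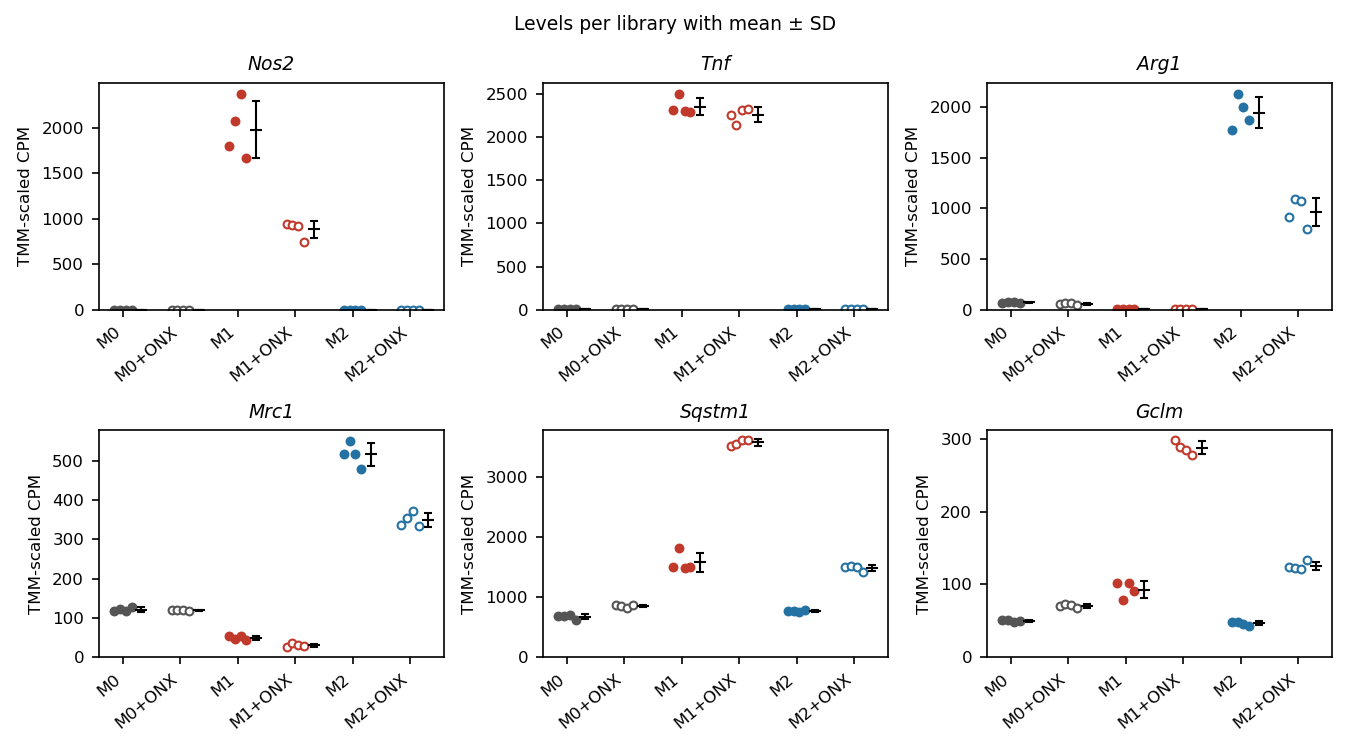
Levels of 6 genes in TMM-scaled CPM on the vertical axis, by group on the horizontal axis; each point is a library and the black mark with its bar is the mean ± SD of 4 libraries. Nos2 is high in M1 and lower in each M1 library with ONX-0914, and Tnf does not differ past the test in M1 (adjusted p = 0.581). Arg1 and Mrc1 are highest in M2, and their means are lower with ONX-0914 in M2 and in M1. Sqstm1 and Gclm are higher with ONX-0914 in each state.

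ONX-0914 in M2 asks what the inhibitor changed in alternatively activated cells. Genes induced by IL-4 fell for 15 of 23 members and rose for 0 (15 adjusted over the list alone, median -0.51, adjusted p = 1.35e-07). Arg1 fell from 1950 ± 156 to 966 ± 140 CPM (SD, n = 4, adjusted p = 2.14e-09). Mrc1 fell from 517 ± 29.5 to 350 ± 18.2 CPM, Retnla from 5.32 ± 0.692 to 2.13 ± 0.635 CPM and Pdcd1lg2 from 32.2 ± 3.12 to 12.8 ± 0.878 CPM. Lower means of Arg1 and Mrc1 with ONX-0914 were not particular to M2. In M1, Arg1 had 8.57 ± 0.961 CPM without and 4.16 ± 0.566 with the inhibitor, and Mrc1 48.5 ± 4.98 and 29.7 ± 4.2. In M0 the means were 72.5 and 58 CPM for Arg1 and 121 and 120 CPM for Mrc1. Chil3 fell from 1560 ± 51.2 to 1320 ± 99.0 CPM (log2 -0.25, adjusted p = 0.013). That call ended without M2 with ONX-0914 replicate 4 (-0.20). Type I interferon-stimulated genes rose for 11 of 28 (12 alone, median 0.47, adjusted p = 0.00337, and adjusted p = 0.67 with an estimated correlation), Oas3 (ENSMUSG00000032661, chromosome 5, 120753098 to 120777661), a sensor of viral RNA, from 11.4 ± 0.843 to 45.2 ± 15.8 CPM. That list call ended without M2 with ONX-0914 replicate 4 (median 0.131).

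Proteasome subunits rose in M2 as well: 14 of 14 in the 20S core (14 adjusted over the list alone, median 1.21, adjusted p = 4.8e-58) and 17 of 18 in the 19S particle (17 alone, median 1.36, adjusted p = 1.54e-95). Psmd11 rose from 56.3 ± 2.33 to 213 ± 6.59 CPM. Of the 5 immunoproteasome and PA28 genes, 3 fell (3 alone, adjusted p = 0.446 for the list). Psmb8 fell from 49.5 ± 2.34 to 41.6 ± 3.43 CPM and Psmb10 from 213 ± 9.52 to 174 ± 6.68 CPM. Psmb9 fell by 0.30 on the log2 scale (adjusted p = 0.0232), and lost the call without M2 replicate 3 (-0.26), M2 replicate 4 (-0.27) or M2 with ONX-0914 replicate 1 (-0.26) or replicate 3 (-0.28). NRF2 antioxidant targets rose for 21 and fell for 1 of 26 (21 and 2 alone, median 0.41, adjusted p = 1.33e-15). Gclm rose from 46.5 ± 2.54 to 126 ± 5.41 CPM, Nqo1 from 2.85 ± 0.701 to 7.94 ± 0.495 CPM and Me1 from 4.23 ± 0.619 to 22.9 ± 2.63 CPM. Sqstm1 rose from 765 ± 20.2 to 1480 ± 43.6 CPM (adjusted p = 1.76e-13) and Keap1 from 42.6 ± 0.944 to 68.3 ± 3.93 CPM, while Nfe2l1 fell from 332 ± 4.76 to 233 ± 4.74 CPM. Cytosolic heat shock genes rose for 18 of 20 (18 alone, median 0.76, adjusted p = 1.99e-26). Hspa1a rose from 2.46 ± 0.414 to 17.6 ± 1.96 CPM. Autophagy and p62 genes rose for 11 and fell for 7 of 27 (11 and 7 alone, adjusted p = 0.0122, and adjusted p = 0.265 with an estimated correlation). Proteasome assembly factors and other activators rose for 3 and fell for 2 of 11 (4 and 2 alone, adjusted p = 0.0209, and adjusted p = 0.21 with an estimated correlation).

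Cholesterol synthesis genes all fell in M2, 18 of 18 (18 adjusted over the list alone, median -0.69, adjusted p = 1.95e-16). Fdft1, a squalene synthase, fell from 39.9 ± 1.59 to 20.6 ± 2.23 CPM. MHC class II genes fell for 9 of 10 (9 alone, median -1.74, adjusted p = 7.07e-16). H2-Aa fell from 23 ± 0.891 to 5.39 ± 0.420 CPM, and B cell markers fell for 10 of 11 (11 alone, median -1.94, adjusted p = 1.1e-06), their sum from 121 ± 4.40 to 65.3 ± 3.51 CPM. ATF4 integrated stress response genes fell for 13 and rose for 2 of 20 (14 and 2 alone, adjusted p = 0.000317, and adjusted p = 0.27 with an estimated correlation). Trib3 fell from 61.5 ± 2.30 to 31.5 ± 1.69 CPM. Cell cycle genes fell for 15 of 25 (18 alone, adjusted p = 0.00207, and adjusted p = 0.186 with an estimated correlation). Matrix proteases and inhibitors rose for 8 and fell for 3 of 19 (8 and 4 alone, adjusted p = 0.0118, and adjusted p = 0.116 with an estimated correlation). Mmp19, a matrix metalloproteinase, rose from 191 ± 3.66 to 625 ± 39.5 CPM. In all, 5345 genes changed, 2586 upward and 2759 downward. Of the 2744 genes higher in M2 than in M0, 953 (34.7%) fell with ONX-0914, where independence would give 515. Of the 2571 lower genes, 619 (24.1%) rose, beside 453 under independence. With 2 of the shared M2 libraries given to each comparison, 992 genes moved against the polarization and 612 with it on average, where all libraries gave 1572 and 945. Simulated groups without change gave 0 genes moved against it. They called 0 genes on average for M2 against M0, so they cannot show how shared libraries act among changed genes.

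The effects of ONX-0914 overlapped across the 3 states, which share no libraries. Between M0 and M2, 2304 genes changed in the same direction (562 under independence) and 28 in opposite directions. Between M1 and M2 the counts were 3534 (1194.5 under independence) and 208, and between M0 and M1 they were 2134 (698 under independence) and 142. Log2 changes correlated across genes at r = 0.459 for M0 and M1, 0.567 for M0 and M2 and 0.597 for M1 and M2, and genes are not independent replicates. In all 3 states 826 genes rose, Uchl1, Nol3, Afp, Psmb5 and Gclm among them, and 1010 fell, H2-Aa, Nfe2l1 and Psmb8 among them, where independence would give 40.9 and 87.4.

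**Figure D4:**
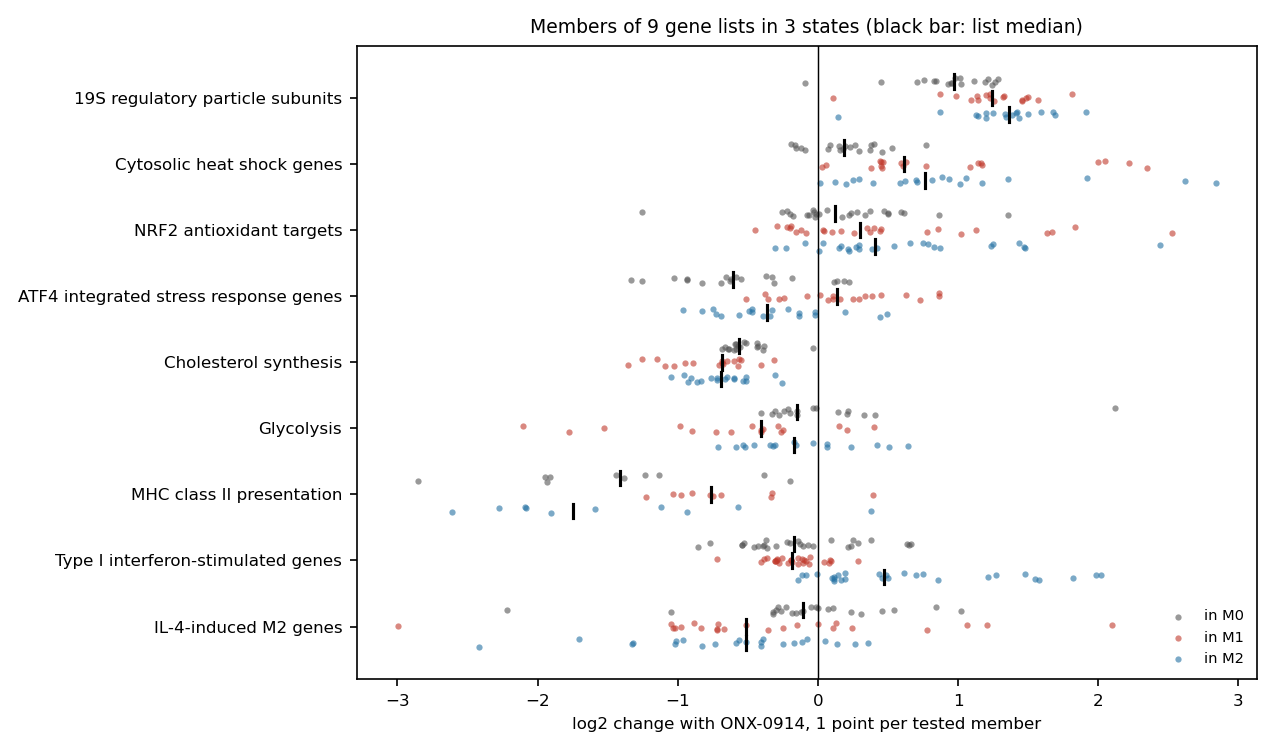
Change with ONX-0914 of the tested members of 9 gene lists, as log2 change on the horizontal axis, by list and state on the vertical axis; each point is a gene and each black bar the median of a list. The 19S and heat shock lists lie to the right and the cholesterol and MHC class II lists to the left in each state, and the median of the ATF4 list is -0.60 in M0, 0.14 in M1 and -0.36 in M2.

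The difference between the effects in M1 and in M0 asks whether the inhibitor acted differently in inflammatory cells, and 2834 genes differed, 1014 upward in M1 and 1820 downward. ATF4 integrated stress response genes differed most as a list: 16 of 20 were higher in M1 relative to M0 (16 up and 3 down adjusted over the list alone, median 0.67, adjusted p = 6.37e-27), with Trib3 at 1.78 ± 0.137 (SE, adjusted p = 4.88e-10) and Chac1 at 1.98 ± 0.178. Heat shock genes followed with 16 of 20 (18 alone, median 0.59, adjusted p = 5.06e-25), led by Hspa1b at 2.05 ± 0.155, and NRF2 targets with 11 up and 1 down of 26 (11 and 1 alone, adjusted p = 6.98e-09). Gclm differed by 1.14 ± 0.0899 (adjusted p = 7.82e-10), Srxn1 by 1.43 ± 0.0673 and Sqstm1 by 0.85 ± 0.0785 (adjusted p = 1.18e-08). ER unfolded protein response genes were higher for 6 of 20 (7 alone, adjusted p = 6.8e-05), and 19S subunits for 12 of 18 (13 alone, adjusted p = 3.2e-09, and adjusted p = 0.0673 with an estimated correlation). MHC class II genes fell less in M1, with 4 of 10 higher and 1 lower (5 and 1 alone, adjusted p = 0.000525, and adjusted p = 0.094 with an estimated correlation), H2-Aa at 0.97 ± 0.103. Without ONX-0914 their summed level was 167 CPM in M0 and 741 CPM in M1. B cells also carry MHC class II, and B cell markers fell in each state. A different response of macrophages therefore cannot be told apart from a loss of B cell signal.

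Other lists differed downward between M1 and M0, apart from autophagy. Glycolysis genes were lower for 11 of 17 (11 adjusted over the list alone, median -0.47, adjusted p = 1.27e-11, and adjusted p = 0.0787 with an estimated correlation), Slc16a3 at -1.83 ± 0.133 (adjusted p = 2.22e-10). Cell cycle genes were lower for 9 of 25 (15 alone, adjusted p = 0.000176, and adjusted p = 0.106 with an estimated correlation). NF-kappaB feedback targets were lower for 5 of 16 (7 alone, median -0.20, adjusted p = 0.0247, and adjusted p = 0.505 with an estimated correlation). That call ended without M1 replicate 2 (-0.13). The autophagy list had 8 members higher and 5 lower of 27 (8 and 7 alone), a median of -0.04, a mean of 0.06 and an upward test at adjusted p = 0.0376, and adjusted p = 0.373 with an estimated correlation. That call ended without M0 with ONX-0914 replicate 4 (median -0.06), M1 replicate 3 (-0.05) or M1 replicate 4 (-0.05). Sla differed by -2.17 ± 0.169, and Mrc1 by -0.70 ± 0.107. Of these genes 35.8% were upward here, 39.7% with DESeq2 size factors and 55.6% with the libraries of the comparison alone.

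Between M2 and M0 the effects differed for 907 genes, 505 upward in M2 and 402 downward, and for 1672 without M1 replicate 2, which is in neither group but enters the common estimate of spread. Heat shock genes were higher in M2 relative to M0 for 13 of 20 (18 adjusted over the list alone, adjusted p = 7.47e-42), Hspa1a by 2.47 ± 0.194 (SE). NRF2 targets were higher for 14 of 26 (16 alone, adjusted p = 5.06e-25), Gclm by 0.94 ± 0.0907 (adjusted p = 1.67e-07) and Sqstm1, the p62 gene, by 0.62 ± 0.0785. The 19S particle was higher for 15 of 18 (18 alone, adjusted p = 4.26e-23) and the 20S core for 11 of 14 (13 alone, adjusted p = 3.4e-14), Psmd11 by 0.63 ± 0.0680. Genes induced by IL-4 were lower for 5 of 23 (8 alone, adjusted p = 2.59e-06), Arg1 by -0.69 ± 0.137 and Mrc1 by -0.55 ± 0.101. Cholesterol synthesis genes were lower for 1 of 18 (1 alone, adjusted p = 0.00868). Interferon-stimulated genes were higher for 4 of 28 (10 alone, median 0.64, adjusted p = 8.31e-09, and adjusted p = 0.27 with an estimated correlation). Their median was 0.33 without M2 with ONX-0914 replicate 4. Smaller list calls that did not hold with an estimated correlation were those of the autophagy (adjusted p = 0.000372, then adjusted p = 0.108 with an estimated correlation), ER (0.00868, then 0.116), ATF4 (5.65e-05, then 0.217), cell cycle (6.8e-05, then 0.0832) and MHC class I lists (0.00254, then 0.264). Of the called genes 55.7% were upward here, 47.4% with DESeq2 size factors and 45.3% with the libraries of the comparison alone.

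Between M1 and M2 the effects differed for 1981 genes, 559 upward in M1 and 1422 downward. ATF4 genes were higher in M1 relative to M2 for 15 of 20 (15 adjusted over the list alone, adjusted p = 4.22e-20), Chac1, a glutathione-degrading enzyme, by 1.56 ± 0.164 (SE), and MHC class II genes for 5 of 10 (7 alone, adjusted p = 2.15e-09). For MHC class II, a loss of B cell signal cannot be told apart here either. Its summed level without ONX-0914 was 741 CPM in M1 and 183 CPM in M2. Keap1, which fell in M1 and rose in M2, differed by -1.01 ± 0.105 (adjusted p = 1.23e-07), and Psma5 by -1.08 ± 0.0874. Interferon-stimulated genes were lower for 11 of 28 (16 alone, median -0.56, adjusted p = 2.33e-08, and adjusted p = 0.284 with an estimated correlation), Oas3 by -2.27 ± 0.199. Their median was -0.291 without M2 with ONX-0914 replicate 4. Glycolysis genes were lower for 10 of 17 (13 alone, adjusted p = 2.74e-11, and adjusted p = 0.0832 with an estimated correlation) and 20S subunits for 7 of 14 (8 alone, adjusted p = 7.33e-07, and adjusted p = 0.163 with an estimated correlation). The same held for NF-kappaB feedback targets, 7 of 16 (8 alone, adjusted p = 0.000544, then adjusted p = 0.264 with an estimated correlation), MHC class I genes, 7 of 14 (8 alone, 9.06e-05, then 0.135), and matrix proteases, 7 of 19 with 1 higher (10 and 1 alone, 0.00192, then 0.0517), with Mmp14 at -0.98 ± 0.0993. ER genes were higher for 4 and lower for 1 of 20 (4 and 1 alone, median 0.03, adjusted p = 0.0259, and adjusted p = 0.186 with an estimated correlation), and lost the call without M2 replicate 2 (0.06). Sqstm1 was not past the test (log2 0.23 ± 0.0783, adjusted p = 0.0534), but passed without M1 replicate 2 (0.30), with DESeq2 size factors (0.27), the DESeq2 Wald test (0.27), limma voom with quality weights (0.30) and the libraries of the comparison alone (0.34). With the libraries of this comparison alone the median of all genes shifted by 0.111 in log2, and 57.8% of called genes were upward in place of 28.2%, where DESeq2 size factors gave 39.2%.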

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

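Leaving out each library for the lists, leaving out M1 replicate 2 as a doubted library, and the change of the screened levels to TMM-scaled CPM were chosen after results had been seen. The screen looked, for each measure, for a library whose gap to the nearest of its group was large beside the group's range (Dixon's test for 4 libraries). It found 26 such cases among 207 pairs of a measure and a group on TMM-scaled CPM, and 17 on unscaled CPM. A rate of 1 in 20 would give 10.3, a rough guide only. The measures are not independent, and a gene with counts in 1 library of a group alone always stands out. Of these, 16 stood out on both scales, 10 on TMM-scaled CPM alone and 1 on unscaled CPM alone. M1 replicate 2 made 7 of the 26, and 4 of the 17.

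M1 replicate 2 had 0.3% of its counts on mitochondrial genes and 13.1% on the 10 most counted genes, and higher Psmb9 (286 CPM, others 208 to 211), Psmb5 (193, others 145 to 150), Psmb6 (687, others 509 to 528), Sqstm1 (1810, others 1480 to 1510) and Tnf (2510, others 2290 to 2310). A mislabelled ONX-0914 library is argued against, since it lay at 0.0843 on the axis from the other M1 libraries (0) to the M1 libraries with ONX-0914 (1). Gene length bias as the whole cause is argued against, since the Spearman correlation across genes of its deviation with transcript length was -0.211, and M0 replicate 4 reached 0.344. A rank correlation does not measure the size of a deviation, so a part for gene length stays open. GC content bias had the value it needs, a Spearman correlation across genes of 0.66 with transcript GC content, where the other 23 libraries reached at most 0.289, and genes are not independent replicates. A bias in how this library was prepared is therefore a candidate explanation, and no biological explanation was tested.

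The effect of ONX-0914 on type I interferon-stimulated genes differed between M1 and M2, with a list median of -0.56. Scaling between libraries is argued against, since the highest list median under 2 other scalings was -0.445. Whether 1 library made the difference stays open, since without 1 of the 16 libraries the list median ranged from -0.697 to -0.291, the latter without M2 with ONX-0914 replicate 4. The mean log2 CPM of the list was 2.85 ± 0.489 in M2 with ONX-0914, and the highest of its 4 libraries had 3.5. A response of M2 cells to the inhibitor may also be present and cannot be told apart from the state of that culture with 4 libraries.

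Other libraries stood apart on 1 to 3 measures each. M1 with ONX-0914 replicate 1 had a total of 22.9 in units of 1e6 (others 18.9 to 19.4), 11.3 CPM of mast cell and basophil markers (14.7 to 15) and 655 CPM of Psmb6 (625 to 630). M2 with ONX-0914 replicate 4 had 20100 genes with a count (19700 to 19800). Summed T and NK cell markers were 25.5 CPM in M1 replicate 3, and mesothelial and fibroblast markers 790 CPM in M1 replicate 1. Psmb8 had 46 CPM in M2 replicate 3, Psmb9 14.5 in M0 replicate 4, Psmb7 58.5 in M2 replicate 4 and Retnla 1.38 in M1 replicate 4. Nos2 had 744 CPM in M1 with ONX-0914 replicate 4 (918 to 944). Near the limit of detection, Nos2 had 0.0414 CPM in M0 replicate 4, 0.0459 in M2 replicate 1 and 0 in M2 with ONX-0914 replicate 4. Il1b had 0.0472 in M0 with ONX-0914 replicate 2, 0.0433 in M2 replicate 3 and 0.0993 in M2 with ONX-0914 replicate 3. Il6 had 0.0828 in M0 replicate 4 and Il12b 0.0867 in M2 replicate 3.

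The effects of ONX-0914 in M1 and M0 differed by the interaction test for 2834 genes and 10 lists. Among the genes reported whatever their result, these were Psmb9 (log2 -0.426), Nfe2l1 (0.239), Nfe2l2 (-0.312), Keap1 (-0.547), Sqstm1 (0.848), Gclm (1.14), Arg1 (-0.724) and Mrc1 (-0.698). Psmb9 lost the call without M0 replicate 4 (-0.33), M0 with ONX-0914 replicate 2 (-0.41) or replicate 3 (-0.38), and with the libraries of the comparison alone (-0.33). Arg1 lost it under limma voom with quality weights (-0.61). Nfe2l1 lost it without M0 replicates 2 or 3 (0.23 each), M0 with ONX-0914 replicates 1 (0.22) or 4 (0.23), M1 replicates 1 (0.21) or 4 (0.20), or M1 with ONX-0914 replicates 2 (0.21) or 3 (0.23).

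Between M2 and M0 the effects differed for 907 genes (1672 without M1 replicate 2) and 12 lists, with Psmb5 (0.386), Psmb7 (0.356), Keap1 (0.467), Sqstm1 (0.62), Nqo1 (0.882), Gclm (0.936), Arg1 (-0.689) and Mrc1 (-0.548). Psmb5 lost the call with DESeq2 size factors (0.36), and without M0 replicates 1 (0.33) or 3 (0.37), M0 with ONX-0914 replicates 2 (0.38), 3 (0.37) or 4 (0.38), M2 replicates 1 (0.40), 3 (0.36) or 4 (0.38), or M2 with ONX-0914 replicates 1 (0.39), 2 (0.36) or 3 (0.37). Psmb7 lost it without M0 replicates 1 (0.32) or 3 (0.34), M0 with ONX-0914 replicates 2 (0.36) or 3 (0.32), M2 replicate 4 (0.32), or M2 with ONX-0914 replicates 1 (0.34), 2 (0.33) or 3 (0.35). Nqo1 lost it without M0 replicates 1 (0.86) or 4 (0.80), M0 with ONX-0914 replicates 1 (0.80) or 3 (0.79), or M2 replicates 2 (0.76) or 3 (0.84).

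Between M1 and M2 they differed for 1981 genes and 9 lists, with Psmb8 (-0.336), Psmb6 (-0.415), Nfe2l1 (0.232), Nfe2l2 (-0.288), Keap1 (-1.01) and Tnf (0.588). The Tnf difference lay mostly in M2, where its level was low. It had 3.87 ± 0.494 CPM in M2 without and 2.47 ± 0.451 with ONX-0914, against 2360 ± 100 and 2260 ± 84.8 in M1. Psmb8 lost the call without M1 with ONX-0914 replicate 1 (-0.31), M2 replicate 3 (-0.30) or M2 with ONX-0914 replicate 2 (-0.28), and Tnf without M2 with ONX-0914 replicate 1 (0.50). With the libraries of the comparison alone Psmb8 (-0.22), Psmb6 (-0.30) and Nfe2l2 (-0.18) lost the call, and with DESeq2 size factors Psmb8 did (-0.29). Nfe2l1 lost it in 14 of the 16 leave-outs, with values of 0.20 to 0.25, and also with no count filter (0.25) or a filter of at least 1 CPM in 4 libraries (0.22).

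In each of the 5 pairwise comparisons, 1 of 35 splits of the same libraries, the real one, gave as many called genes. That is the lowest share that 35 splits can give. Splits that mix 2 differing groups also widen the spread and so lower the other counts, and chance is not excluded by them. The real counts and the highest of the others were 3079 and 2 for ONX-0914 in M0, 6514 and 1460 in M1, 5345 and 0 in M2, 10114 and 1909 for M1 against M0, and 5315 and 0 for M2 against M0. For the differences the splits decide nothing, since exchanging inhibitor labels within a state moves the effects of ONX-0914 themselves into the difference or into the spread. There 2 of 100 splits gave at least 2834 genes between M1 and M0 (highest other 3768), 4 of 100 at least 907 between M2 and M0 (6117), and 4 of 100 at least 1981 between M1 and M2 (5400).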

How the results depend on the processing

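Leaving out M1 replicate 2 as a doubted library, leaving out libraries for lists and overlaps, and DESeq2 size factors for lists were chosen after results were seen. With a minimum log2 change of 1, called genes were 263 for ONX-0914 in M0, 950 in M1, 617 in M2, 4152 for M1 against M0 and 930 for M2 against M0. For the differences they were 435 between M1 and M0, 81 between M2 and M0 and 246 between M1 and M2. Genes shared in direction were then 137 for M0 and M1, 156 for M0 and M2 and 305 for M1 and M2, and with this minimum on the polarization change alone, genes moved against polarization were 1283 in M1 and 242 in M2. With no minimum and 2 of the shared M2 libraries given to each comparison, 992.17 genes moved against polarization in M2 on average, against 1572. limma voom with quality weights called 4622 genes for ONX-0914 in M0 and 1847 for the difference between M2 and M0, and the libraries of that comparison alone called 1590. For ONX-0914 in M1, the libraries of the comparison alone called 4784 genes, 4480 of them also called in the same direction in the main fit. Of 264 list tests, 92 passed camera at the preset correlation, 45 with an estimated correlation, 172 by fry in direction and 220 by its mixed form. Without 1 library, called genes ranged from 2463 to 4340 for ONX-0914 in M0, 5968 to 6804 in M1, 4654 to 6384 in M2, 9809 to 10444 for M1 against M0 and 4739 to 6348 for M2 against M0. The differences ranged from 2448 to 3729 between M1 and M0, 660 to 1672 between M2 and M0, and 1635 to 2576 between M1 and M2. The highest was without M1 replicate 2 each time. With a replicate block the counts were 3131, 6558, 5390, 10151, 5364, 2887, 979 and 2046. The replicate numbers gave no sign of pairing: same-number correlations across genes ran from -0.0518 to 0.108, and 17 of 60 were highest with the own number. Pools of mice shared between groups are not excluded by this. Leaving fry aside, 204 of 264 list results never changed their call, 47 weakened and 13 strengthened under an alternative. Of 1066 results of named genes these were 919, 133 and 14. Among called results 0 reversed, and changes of sign in results that were not called were not counted. Such changes occurred: Il1b with ONX-0914 in M2 had log2 0.78, and -1.50 without M2 with ONX-0914 replicate 3. The cause of these changes was not tested.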

Other observations

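The tests of the B cell pattern below were chosen only after the result was seen. ONX-0914 lowered B cell markers in each state, their sum to 64.6 ± 2.97 CPM from 116 ± 4.41 in M0, and the most abundant of them in M0 were Cd22 (85.6 CPM), Ighm (15.4) and Igkc (3.49). Since Cd22 made up most of that sum, the sum follows this gene more than the other markers. It is not a measure of B cell content. In M0, fewer cells of every other type is argued against, since mesothelial and fibroblast markers had a median log2 change of 0.0742. This was not tested in M1, where the summed markers of the other types had lower means: T and NK cell markers from 21.6 to 11.6 CPM, neutrophil markers from 149 to 116, mast cell and basophil markers from 25.2 to 13.97, eosinophil markers from 8.68 to 5.94, dendritic cell markers from 10.8 to 7.74, and mesothelial and fibroblast markers from 930.5 to 856. Outside M1 the means went both ways. In M0, T and NK cell markers had 5.25 and 3.54 CPM without and with ONX-0914, mast cell and basophil markers 4.67 and 3.41, eosinophil markers 18.2 and 15.1, dendritic cell markers 3.73 and 3.73 and neutrophil markers 53.9 and 60.4. In M2 they had, in the same order, 3.51 and 2.996, 7.21 and 5.09, 17.9 and 12.9, 4.93 and 5.08, and 70.9 and 81.5. Fewer B cells in the treated cultures stays a candidate explanation, and lower transcription in the cells that remained cannot be told apart from it. At least 10 of the 11 markers were called lower in each of the 3 states. That count restates the pattern itself and so cannot decide between them. Erythroid markers had 0.286 and 0.192 CPM in M1.

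Several groups of genes not described above moved in both directions. Of 18 genes of p53 and apoptosis, 5 rose and 8 fell with ONX-0914 in M1 (7 and 8 adjusted over the list alone, list adjusted p = 0.961), and 8 rose and 4 fell in M2 (9 and 5 alone, 0.552). Bcl2l1, a survival gene, fell in M1 from 128 ± 7.90 to 60.2 ± 1.55 CPM (n = 4), while the death genes Pmaip1 and Bcl2l11 rose from 8.26 ± 3.46 to 16.2 ± 2 CPM and from 9.72 ± 0.874 to 16.9 ± 1.61 CPM. Of 21 lysosome genes, 4 rose and 8 fell in M1 (4 and 9 alone, 0.985), with Gaa up from 238 ± 28.9 to 475 ± 9.01 CPM. Of 15 immediate early genes, 4 rose and 5 fell in M1 (5 and 5 alone, 0.842), with Fosl1 up from 7.26 ± 0.955 to 26.9 ± 3 CPM and Ier2 down from 31.8 ± 2.86 to 12.1 ± 1.12 CPM. Of 24 genes of resident macrophage identity, 4 rose and 6 fell in M1 (4 and 6 alone, 0.576), Csf1r from 306 ± 33.4 to 179 ± 10.3 CPM and Gata6 from 11.6 ± 1.06 to 6.90 ± 1.04 CPM.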
